A study of Papio anubis with 12 samples.

How the data were processed

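Small RNA libraries had been made from total RNA of fetal baboon frontal cortex with a column kit and Illumina's small RNA preparation kit, per the labels' protocols, 1 library per fetus. The labels gave diet and sex for all 12 fetuses and named no mother, batch or sequencing date, so replicate numbers follow the order of the records and pair no fetuses. One table with 2234 entries was used, each pairing a human miRBase mature miRNA with a precursor. The aligner and counter are not given in the sources used here; the human build hg18 is named in the submitters' processing notes with no stated role. Per the file headers and the values, the authors deposited normalised levels for each fetus in reads per 1000000 (RPM): each column sums to 1000000 and is rounded to 2 decimals. The table also held the authors' deposited pooled read count per entry, and unadjusted p-values that the authors deposited for 3 diet comparisons. Those p-values equal an unpaired equal-variance test on RPM, recomputed here to within 5e-10.

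Whole reads were recovered from the RPM steps: in every library 100% of values above 0 lay within 0.0051 RPM of a whole number of reads. These reads summed to 513029 to 1898763 per control library and 1078720 to 1464660 per MNR library, and the precision of low values follows from 1 read being worth 0.527 to 1.95 RPM. Read counts carry no molecular identifiers, so intervals and floors cover counting error only. A mature miRNA with several precursors had its reads in several entries, which made 38.5 to 44.3% of the summed reads repeats. Of 1921 mature names, 202 were in several entries, and the entry with most reads was kept for each. In an overlapping set, 133 names with reads fell into 30 groups that shared all values, so such names, and near-identical family members (let-7, miR-10, miR-125, miR-320, miR-548), cannot be fully told apart. Human names stand for the baboon miRNAs that matched them. Genome coordinates were not used here, since the one reference table at hand (Panubis1.0 gene names) is of another assembly. Every pair of libraries differed far beyond sampling noise (smallest chi-square per degree of freedom 28.2), so none was counted as a repeat.

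The test fixed before the data were examined was edgeR for raw counts, or limma for normalised values; since the values were RPM, limma with a trend was fitted to log2(RPM + 1) of the 481 miRNAs with a mean of at least 1 RPM over all fetuses, with Benjamini-Hochberg adjusted p under 0.05 as threshold. Log2 differences are on that scale, which understates changes of low miRNAs. Diet was tested over all 12 fetuses. The tests within females, within males, of the difference between sexes and of sex used the 4 sex by diet cells of 3 fetuses in 1 fit. For 22 miRNA lists fixed beforehand, camera with a preset correlation of 0.01 was run on the 18 with at least 3 measured members; camera with an estimated correlation and fry stood beside it. camera compares the test statistics of a list with those of the other miRNAs, so its direction need not follow the list's median log2 difference. Lists with a median above 0 and a camera direction of down were astrocyte, vessel and mesenchyme, ependyma, muscle, insulin and lipid, and miR-181 and miR-30. The medians of ependyma, muscle, and insulin and lipid even lay above that of all tested miRNAs (by 0.078, 0.049 and 0.0069). The mean of the vessel list was itself below 0 (-0.11). fry, which tests a list's own direction and takes in the shift of all miRNAs, had adjusted p of 0.0003 for the Drosha- or Dicer-independent list, 0.0164 for erythroid, and 0.0456 to 0.0471 for let-7, fragments, oligodendrocyte and mirtrons. Totals, detection and shares were compared with exact two-sided permutation tests of means, adjusted over 7 measures. The table gives no class of non-canonical miRNA, so that comparison rests on the fixed lists of mirtrons and of Drosha- or Dicer-independent miRNAs.

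The miRNAs named were chosen by a rule fixed beforehand. It takes the 10 most abundant, up to 25 past the threshold over all fetuses, and up to 10 past it (or the 3 of smallest p) in each other comparison. It adds the 2 most abundant and any called members of each list, the 5 most abundant non-canonical miRNAs, and the 5 of smallest p in each deposited test. Others are said to have been chosen after their values were seen, or are the remaining members of a short list and the closest misses (miR-328).

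The fit was tested on simulated reads of the 481 miRNAs for the comparison of 6 with 6 fetuses, 200 of them changed, in 20 simulations at a dispersion of 0.0571. It recovered 83.2% of 2-fold and 95.9% of 4-fold changes, with 2.37% false calls among calls and 0.05 calls on average when nothing changed. Every simulated miRNA had the same dispersion, and changes went up and down in equal numbers with no common shift. These rates therefore need not hold for the deposited values, which had such a shift and unequal spread. Alternatives were other scalings (median-ratio, without the 5 most abundant), filters (none, a mean of 10 RPM) and pseudocounts of 0.1 and 5. A threshold of 0.1, sex as a covariate, each sex alone and each fetus left out were also planned. Added after seeing the data were edgeR, DESeq2 and voom on recovered reads, TMM on RPM, every entry in place of 1 per mature miRNA, equal profiles counted as 1, and control replicates 3 and 6 left out together. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0 were used. The authors' group means and standard errors in the table were not used.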

Results

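Small RNA sequencing profiled mature microRNAs (miRNAs) in the frontal cortex of 12 baboon fetuses (Papio anubis) taken on day 165 of gestation. In 6 fetuses the mother had fed freely (controls), and in 6 the mother was nutrient restricted (MNR) and received 70% of the feed that controls ate per kilogram of body weight. Each diet held 3 female fetuses (replicates 1 to 3) and 3 male fetuses (replicates 4 to 6), with 1 library per fetus. The libraries held 1363856, 1810580, 1898763, 840528, 1494844 and 513029 counted reads in control replicates 1 to 6. They held 1245531, 1277351, 1464660, 1078720, 1185188 and 1238462 in MNR replicates 1 to 6. A single read was worth between 0.527 reads per 1000000 counted reads (RPM) in control replicate 3 and 1.95 RPM in control replicate 6, the shallowest library. Of 1921 mature miRNA names, 764 had at least 1 read, and 481 reached a mean of 1 RPM over all fetuses and were tested.

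The most abundant miRNA of the cortex libraries was miR-9-5p, a miRNA of neural progenitors and neurons, at a mean of 77358 RPM over all fetuses, followed by miR-181a-5p at 72900 RPM and miR-26a-5p at 57569 RPM. Then came miR-143-3p (24472 RPM), a smooth muscle miRNA, let-7a-5p (19066 RPM), the neuron-enriched miR-128 (18403 RPM) and miR-191-5p (17781 RPM). The 10 most abundant also included let-7f-5p, miR-22-3p and the imprinted miR-127-3p at 17238, 16491 and 16254 RPM. None of these 10 passed the test for diet. The 10 together took 56.8 ± 1.58% of mature miRNA reads in MNR and 59.7 ± 2.62% in controls (SD, n = 6 per diet; exact permutation test, two-sided, p = 0.0195, adjusted p = 0.0341 over 7 measures of depth and composition). Of the 10, miR-26a-5p showed the widest gap between diets, at 75129 ± 38885 RPM in controls and 40008 ± 8084 RPM in MNR (SD, n = 6; log2 difference -0.79, limma adjusted p = 0.082), and control replicate 3 alone stood at 148140 RPM. DESeq2 on recovered reads called miR-26a-5p lower (-1.15, adjusted p = 0.0079), as did limma without control replicate 1 (-0.95, adjusted p = 0.0292), while edgeR and voom did not call it. Total reads (exact p = 0.762), miRNAs with at least 1 read (558.7 in MNR and 539.5 in controls, exact p = 0.212) and miRNAs with at least 10 reads (355.0 and 336.3, exact p = 0.318) did not pass for diet.

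The main comparison asked which miRNAs differ in the fetal frontal cortex when the mother is nutrient restricted. In RPM, 13 of the 481 tested miRNAs differed between diets, 12 higher and 1 lower in MNR. The strongest was miR-451a (MIMAT0001631), an erythroid miRNA matured without Dicer, which rose from 244 ± 81.5 RPM in controls to 547 ± 113 RPM in MNR (SD, n = 6 per diet). The liver-abundant miR-122-5p (MIMAT0000421), tied to lipid metabolism, fell from 3.54 ± 3.29 to 0.228 ± 0.559 RPM. Higher in MNR were also let-7i-5p and let-7d-5p, members of a family linked to differentiation, the neuron-enriched miR-129-5p, the neural miR-125a-5p, and miR-134, miR-377-5p and miR-154-5p of the imprinted DLK1-DIO3 cluster.

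The log2 difference of miR-451a was 1.2 ± 0.21 (SE; limma with Benjamini-Hochberg adjustment, adjusted p = 0.0093), and every MNR fetus (381 to 705 RPM) lay above every control (155 to 359 RPM). let-7i-5p (MIMAT0000415) stood at 4842 ± 1094 RPM in controls and 8026 ± 1942 RPM in MNR, a log2 difference of 0.73 ± 0.17 (SE; adjusted p = 0.0436). miR-125a-5p (MIMAT0000443) went from 5966 ± 1017 to 8617 ± 1000 RPM, miR-129-5p (MIMAT0000242) from 951 ± 120 to 1371 ± 169 RPM, and let-7d-5p (MIMAT0000065) from 470 ± 87.4 to 687 ± 97.6 RPM (SD, n = 6), with log2 differences of 0.54, 0.53 and 0.55. miR-134 (MIMAT0000447), which neuronal activity regulates, was at 96.2 ± 28 RPM in controls and 167 ± 26.1 RPM in MNR. Its cluster neighbours miR-377-5p (MIMAT0004689) and miR-154-5p (MIMAT0000452) went from 30.4 ± 5.97 to 56.7 ± 15.2 RPM and from 11.6 ± 4.32 to 24.8 ± 7.20 RPM. The log2 differences of these 3 cluster members were 0.83, 0.86 and 1.06. Also higher were miR-1307-5p (MIMAT0022727; 338 ± 65.7 to 502 ± 46.8 RPM), miR-185-5p (MIMAT0000455; 50.1 ± 13.4 to 85.6 ± 17.5 RPM) and miR-877-5p (MIMAT0004949; 13.8 ± 5.64 to 26.3 ± 5.06 RPM), a mirtron, that is, a miRNA spliced from a short intron. In all 12 higher miRNAs, 6 of 6 MNR fetuses lay above the control median, and in miR-122-5p 0 of 6 did. The adjusted p of the 11 calls other than miR-451a and miR-877-5p lay at 0.0436 or 0.047, and that of miR-877-5p at 0.0494.

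**Figure D1:**
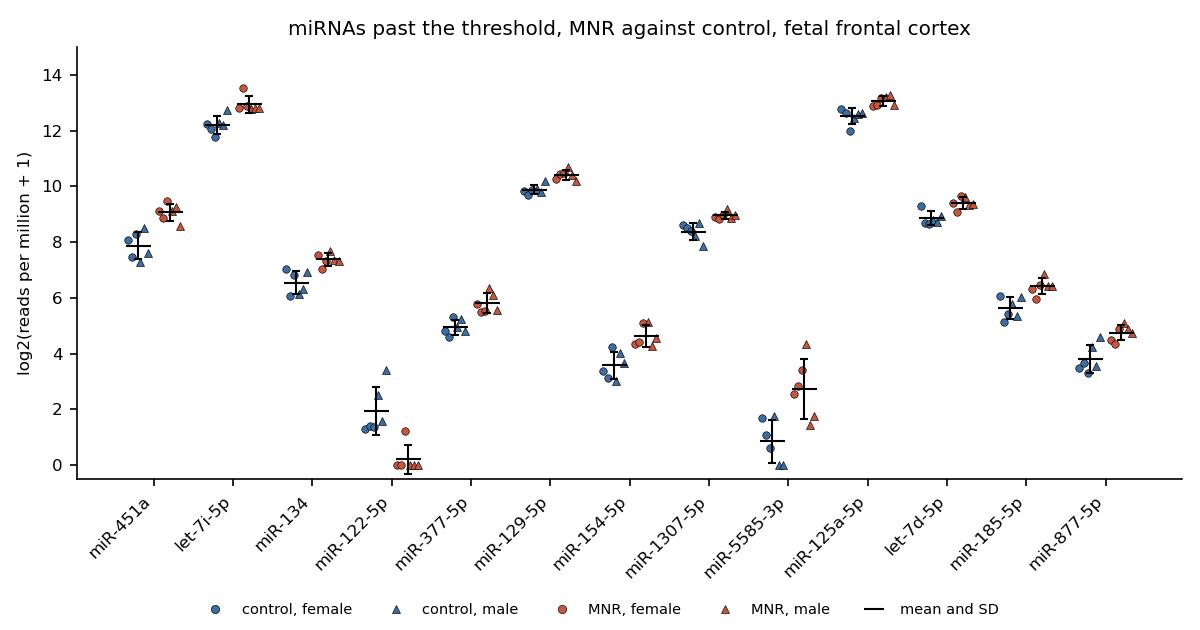
Level of each of the 13 miRNAs past the threshold, as log2(RPM + 1), in single fetuses of the control (blue) and MNR (red) diets, with circles for females, triangles for males, a line for the mean and bars for the SD (n = 6 per diet). miR-451a lies above all controls in every MNR fetus, and miR-122-5p is at 0 in 5 of the 6 MNR fetuses.

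The calls at the lowest levels rested on few reads. miR-122-5p had 20 reads over the 6 controls and 2 over the 6 MNR fetuses, a ratio of 9.46 (exact 95% confidence interval 2.30 to 83.4, counting error only). miR-5585-3p (MIMAT0022286) had 8 reads in controls and 54 in MNR, a ratio of 7.14 (3.38 to 17.4), or 1.04 ± 1.06 and 7.37 ± 6.57 RPM (SD, n = 6). Just outside the threshold lay miR-320a, from 536 ± 131 to 801 ± 90.2 RPM (log2 difference 0.61), and miR-328, from 146 ± 39.3 to 232 ± 44.8 RPM (0.68), both with a limma adjusted p of 0.0502.

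Most of the differences in RPM pointed up. The median log2 difference over all 481 miRNAs was 0.23, and 78.4% of them were above 0; at an unadjusted p under 0.05, 93 miRNAs were higher and 12 lower. Relative to that median, the 12 higher calls lay 0.30 (miR-129-5p) to 1.64 (miR-5585-3p) above it, with miR-451a at 0.97, and miR-122-5p lay at -1.96. Under median-ratio scaling, which set the MNR libraries on average 0.22 lower relative to controls on the log2 scale, 3 miRNAs passed: miR-451a (0.98, adjusted p = 0.0339) higher, and miR-122-5p (-1.82, adjusted p = 0.0447) and miR-421 (-0.74, adjusted p = 0.0169) lower. miR-421, named here after its values were seen, was at 291 ± 40.9 RPM in controls and 205 ± 42.4 RPM in MNR (SD, n = 6; limma adjusted p = 0.0891 in RPM). On recovered whole reads, edgeR called miR-451a higher and miR-421 and miR-10a-5p lower, DESeq2 called 5 higher and 5 lower, and voom 5 higher and 2 lower. miR-451a was past the threshold in all 28 alternatives tried, miR-122-5p in 13 of the 24 that tested it, and each other called miRNA in 3 to 12. Leaving out control replicate 2, 3 or 5 or MNR replicate 1, 4, 5 or 6 left miR-451a as the 1 call, leaving out control replicate 4 or MNR replicate 3 left 2 calls, and leaving out control replicate 1 gave 26. With each fetus left out all 13 kept their direction (miR-451a at 1.08 to 1.33, let-7i-5p at 0.61 to 0.83), and the highest adjusted p among them was 0.108.

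**Figure D2:**
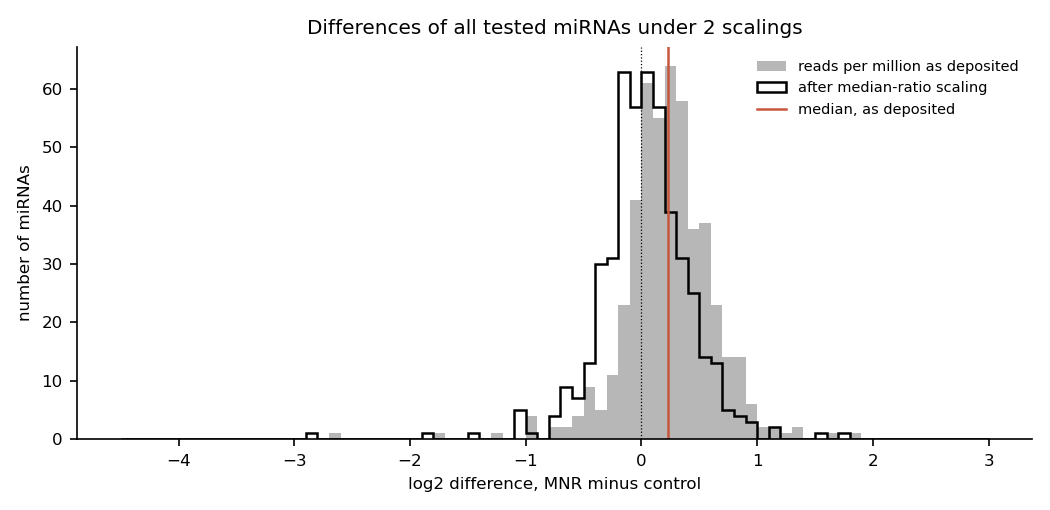
Histogram of the log2 difference between MNR and control over the 481 tested miRNAs (x axis, log2; y axis, number of miRNAs), in RPM as deposited (grey) and after median-ratio scaling (outline). The median in RPM (red line) lies at 0.23.

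Among miRNAs of neurons and of the tissue itself, single members passed the test and no list did with camera. With fry, which takes in the shift of all miRNAs, the let-7 family passed (adjusted p = 0.0456). The neuron-enriched list had 21 measured members, of which miR-129-5p rose (1 also adjusted over the list alone), while miR-9-5p (75172 and 79544 RPM in controls and MNR) and miR-128 (16151 and 20654 RPM) did not pass (camera adjusted p = 0.758). Of 7 activity-regulated miRNAs, miR-134 rose (1 adjusted over the list alone), and miR-132-3p (1108 ± 333 and 1573 ± 618 RPM) and miR-212-3p (133 ± 35.5 and 133 ± 50 RPM) did not pass (adjusted p = 0.523). In the let-7 family, 2 of 17 members passed and 5 did when adjusted over the list alone; let-7a-5p was at 16526 ± 2175 RPM in controls and 21606 ± 2061 RPM in MNR, and let-7f-5p at 16709 ± 2868 and 17768 ± 835 RPM (list adjusted p = 0.389). The imprinted DLK1-DIO3 cluster had 66 measured members, 3 of them higher by either adjustment, with miR-127-3p (15314 ± 2599 and 17193 ± 2869 RPM) and miR-410 (3336 ± 802 and 3101 ± 609 RPM) not past the threshold (list adjusted p = 0.651). The proliferation-linked miR-17-92 family (20 members, 0 called, led by miR-92a-3p at 1941 and 2473 RPM; adjusted p = 0.864) and the miR-181 and miR-30 families (19 members, 0 called; adjusted p = 0.523) had no member past the threshold by either adjustment. None of the 8 hypoxia and stress miRNAs passed by either adjustment, among them miR-22-3p (14911 ± 3320 and 18071 ± 4198 RPM) and miR-199a-3p (212 ± 40.7 and 321 ± 141 RPM) (list adjusted p = 0.651). Of 23 insulin and lipid miRNAs, miR-122-5p fell (1 adjusted over the list alone), and miR-143-3p (25632 and 23311 RPM) and miR-103a-3p (5139 and 5767 RPM) did not pass (list adjusted p = 0.651).

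Lists for other cell types the tissue could hold were also tested, and none passed with camera. With fry, which takes in the shift of all miRNAs, erythroid (adjusted p = 0.0164) and oligodendrocyte (adjusted p = 0.0459) passed. The erythroid list had 5 measured members, with miR-451a higher (1 adjusted over the list alone), a median log2 difference of 0.64 and a camera adjusted p of 0.102. Its other members were miR-486-5p at 2742 ± 587 RPM in controls and 3513 ± 932 RPM in MNR, miR-144-3p at 34.8 ± 17.1 and 52.1 ± 17.2 RPM, miR-144-5p at 15.6 ± 6.58 and 19.4 ± 4.64 RPM, and miR-486-3p at 2.21 ± 1.42 and 4.38 ± 1.62 RPM (SD, n = 6), none past the threshold. The vessel and mesenchyme list (14 members) had 0 calls and, adjusted over the list alone, 1 lower miRNA, miR-10a-5p; miR-126-5p of endothelium was at 6126 ± 1781 and 6165 ± 2229 RPM (list adjusted p = 0.238). Both measured members of the hindbrain HOX list, miR-10a-5p (208 ± 317 and 11.6 ± 5.81 RPM) and miR-10b-5p (2680 ± 2198 and 1087 ± 701 RPM), were lower when adjusted over the list alone and neither over all miRNAs, and control replicate 6 held 821 RPM of the first and 6908 RPM of the second. No member passed by either adjustment among 11 oligodendrocyte (miR-138-5p at 1073 and 1236 RPM, miR-23a-3p at 272 and 355 RPM, adjusted p = 0.758), 14 astrocyte (miR-26b-5p at 1273 and 1593 RPM, adjusted p = 0.389), 8 microglia and leukocyte (miR-342-3p at 1168 and 1260 RPM, miR-146a-5p at 282 and 325 RPM, adjusted p = 0.758), 5 ependyma and choroid plexus (miR-204-5p at 1091 and 1176 RPM, miR-211-5p at 8.82 and 13.9 RPM, adjusted p = 0.758) and 4 muscle miRNAs (miR-1 at 67.9 and 92.7 RPM, miR-133a at 45.8 and 72.7 RPM, adjusted p = 0.758). The 2 epithelial miRNAs (miR-141-3p and miR-200b-3p, both under 3 RPM on average) and the 2 of the sensory cluster (miR-182-5p at 23.1 and 22 RPM, miR-183-5p at 6.46 and 7.06 RPM) were too few to test and held 0 calls. No member of the placental C19MC cluster reached the level needed for a test. The abundant miR-9-5p, miR-181a-5p, let-7f-5p, miR-127-3p, miR-93-5p and miR-181c-5p, none past the threshold, turned from slightly above to below 0 under median-ratio and TMM scaling.

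**Figure D3:**
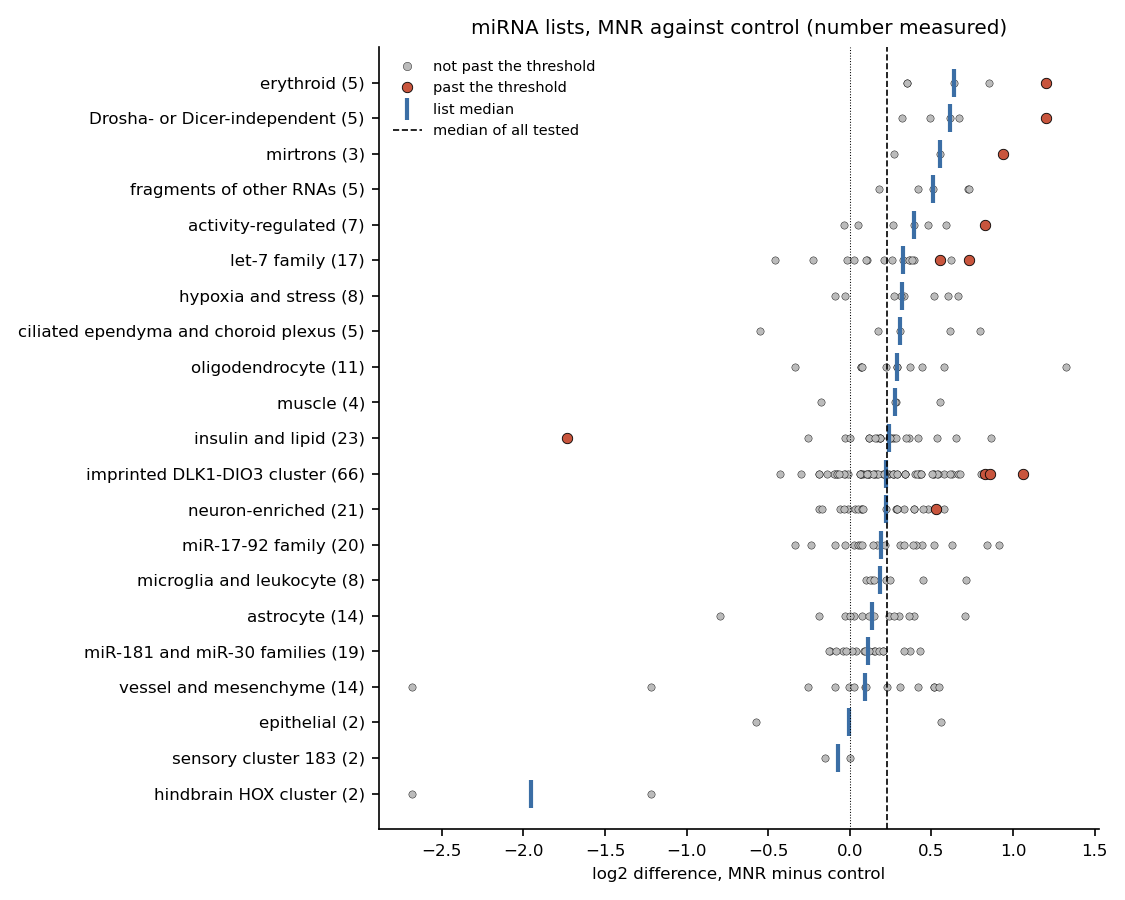
Log2 difference between MNR and control (x axis) of each measured miRNA in 21 fixed lists (y axis, number measured in brackets), with members past the threshold in red, list medians as blue bars and the median of all tested miRNAs (0.23) as a dashed line. The erythroid and Drosha- or Dicer-independent medians lie at 0.64 and 0.61, and the hindbrain HOX pair lies at -1.95.

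miRNAs matured outside the canonical pathway, the subject of the series title, took more of the MNR libraries. The Drosha- or Dicer-independent miRNAs (miR-451a, miR-320a, miR-320b, miR-320c and miR-484) held 0.318 ± 0.0230% of mature miRNA reads in MNR and 0.204 ± 0.0295% in controls (SD, n = 6 per diet; exact permutation test, two-sided, p = 0.00216, the smallest these 12 fetuses allow, adjusted p = 0.0152). Mirtrons held 0.00981 ± 0.00256% and 0.0060 ± 0.0018% (exact p = 0.0152, adjusted p = 0.0341). Both shares take in the upward shift of most miRNAs in RPM (median log2 difference 0.23), which these tests do not remove. Of the 5 Drosha- or Dicer-independent miRNAs, miR-451a was called over all miRNAs and 3 passed adjusted over the list alone, with miR-484 at 374 ± 84.0 RPM in controls and 457 ± 43.1 RPM in MNR, and miR-320b at 23.9 ± 7.59 and 33.0 ± 6.64 RPM. This was the 1 list past the threshold among 18 tested (median log2 difference 0.61; camera adjusted p = 0.0192), and it did not hold with an estimated correlation (adjusted p = 0.131 with an estimated correlation). Without control replicate 6 its camera adjusted p was 0.0542, and it did not pass without MNR replicate 2. Of 3 measured mirtrons, miR-877-5p rose (1 adjusted over the list alone) and miR-1224-5p (18.4 ± 7.33 and 27.2 ± 10.3 RPM) did not pass (list adjusted p = 0.389). So 2 of the 13 calls were non-canonical by these lists, and under median-ratio scaling 1 was, miR-451a.

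Entries that lie in tRNA, snoRNA or other RNAs, which can also mark RNA degradation, moved the same way. Their share was 0.0831 ± 0.0104% in MNR and 0.0603 ± 0.0115% in controls (SD, n = 6, exact permutation p = 0.00866, adjusted p = 0.0303). The common upward shift in RPM is part of this difference as well and was not removed. None of the 5 passed over all miRNAs and 2 did adjusted over the list alone; miR-1260b was at 101 ± 26.9 and 163 ± 25.2 RPM, and miR-664-3p at 141 ± 56.8 and 151 ± 22.2 RPM (list camera adjusted p = 0.238). Of the shares, that of the 10 most abundant miRNAs and those of mirtrons and fragments lost the threshold when certain single fetuses were left out. Without control replicate 2, 4 or 5 or MNR replicate 3 or 5, the Drosha- or Dicer-independent share was the 1 measure past it, and without MNR replicate 4 there were 2.

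**Figure D4:**
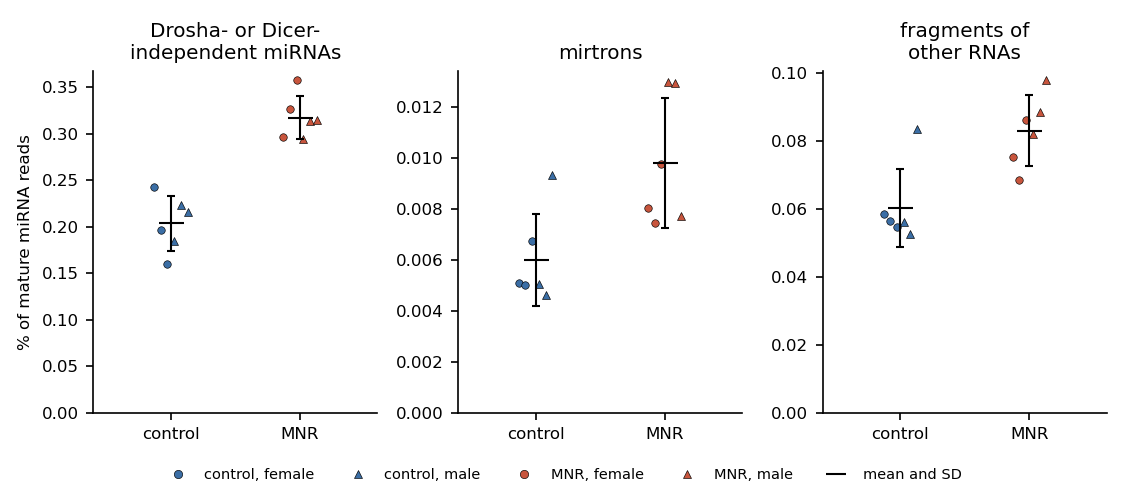
Share of mature miRNA reads (y axis, percent) on Drosha- or Dicer-independent miRNAs, mirtrons and fragments of other RNAs in single control (blue) and MNR (red) fetuses, with circles for females, triangles for males, a line for the mean and bars for the SD (n = 6 per diet). The first share averaged 0.318% in MNR and 0.204% in controls, with no overlap between diets.

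The diet comparison within sexes asked whether female and male fetuses differed in their response. In males, 8 miRNA names, which stood for 5 distinct profiles, were lower in MNR. They were miR-10a-5p (381 ± 401 RPM in control and 11 ± 2.56 RPM in MNR males), miR-10b-5p (3968 ± 2593 and 816 ± 692 RPM), miR-122-5p (5.51 ± 3.92 and 0 RPM), miR-548h-5p (7.66 ± 0.462 and 1.72 ± 0.122 RPM) and a single profile shared by miR-548am-5p, miR-548au-5p, miR-548c-5p and miR-548o-5p (9.62 ± 2.31 and 2.53 ± 1.31 RPM; SD, n = 3 per diet). miR-10a and miR-10b sit in HOX gene clusters, and miR-548 is a large primate family. In females no miRNA passed; the smallest p belonged to let-7i-5p (4192 ± 710 RPM in control and 8940 ± 2628 RPM in MNR females), miR-708-5p (165 ± 21.5 and 347 ± 126 RPM) and miR-451a (252 ± 68.4 and 576 ± 120 RPM).

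All 8 male calls had a limma adjusted p of 0.0366, with log2 differences of -4.13 (miR-10a-5p), -2.51 (miR-122-5p), -2.40 (miR-10b-5p), -1.67 (miR-548h-5p) and -1.63 (the shared miR-548 profile). Control males held 12 reads of miR-122-5p and MNR males 0, so it was at least 4.92-fold lower against a floor of 3 reads over the group (0.857 RPM, counting error only). The miR-548 calls also rested on few reads: 22 in control and 6 in MNR males for miR-548h-5p (control over MNR 4.51, exact 95% interval 1.77 to 13.6), with an SD in RPM smaller than 1 read, and 27 and 9 for the shared profile (3.69, 1.68 to 8.92). Control replicate 6 held the highest level of the 12 fetuses for miR-10a-5p, miR-10b-5p and miR-122-5p (9.75 RPM). Without it, as without any one of control replicates 1, 2 and 4 or MNR replicates 1, 3 and 5, no male call was left; without MNR replicate 4 there was 1 and without MNR replicate 6 there were 4. The male log2 differences stayed below 0 throughout: without control replicate 6 they were -3.13 ± 0.825 (SE) for miR-10a-5p, -2.06 ± 0.520 for miR-122-5p, -1.90 ± 0.562 for miR-10b-5p, -1.66 ± 0.404 for miR-548h-5p and -1.49 ± 0.410 for the shared miR-548 profile (limma adjusted p from 0.107 to 0.14). Without a female fetus they were the same as with all 12, and the adjusted p of the lost calls lay between 0.0515 and 0.0633. Median-ratio scaling gave 9 male calls and TMM scaling 8, all lower, and on recovered reads edgeR made 0, DESeq2 2 and voom 1. At an unadjusted p under 0.05, 64 miRNAs were higher and 15 lower in MNR males.

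In females the limma adjusted p was 0.0859 for let-7i-5p (log2 difference 1.07), 0.138 for miR-708-5p (1.02) and 0.189 for miR-451a (1.21). At an unadjusted p under 0.05, 49 miRNAs were higher and 0 lower, and edgeR, DESeq2 and voom made 0 calls. Without MNR replicate 1, let-7i-5p and miR-708-5p passed (2 calls). The female values were 36.1 ± 36.1 RPM in controls and 12.3 ± 8.74 RPM in MNR for miR-10a-5p, and 1393 ± 614 and 1358 ± 726 RPM for miR-10b-5p (SD, n = 3).

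**Figure D5:**
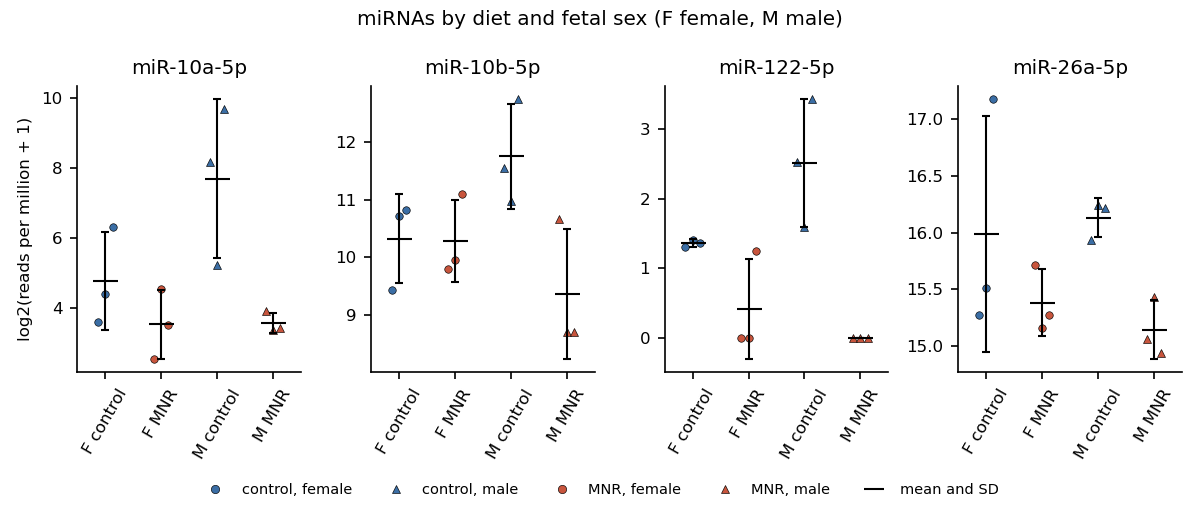
Levels of miR-10a-5p, miR-10b-5p, miR-122-5p and miR-26a-5p as log2(RPM + 1) (y axes) in single fetuses by sex and diet (x axis), with circles for females, triangles for males, control in blue, MNR in red, a line for the mean and bars for the SD (n = 3). Means in males are 381 and 11 RPM for miR-10a-5p, and in females 36.1 and 12.3 RPM.

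The test of the difference itself found no miRNA whose response to diet differed between sexes. limma made 0 calls (smallest adjusted p = 0.77), with 24 miRNAs at an unadjusted p under 0.05, and edgeR, DESeq2 and voom made 0. The smallest p belonged to miR-450a-5p (log2 difference of the male and female responses 2.42), miR-548h-5p (-1.83) and miR-10b-5p (-2.36). miR-450a-5p was at 1.69 ± 1.47 RPM in control and 6.33 ± 0.956 RPM in MNR males, and at 2.36 ± 0.352 and 0.983 ± 0.335 RPM in females (SD, n = 3). Across the 481 miRNAs, which are not independent replicates, the male and female responses had a Pearson r of 0.241 and a Spearman rho of 0.18, and 314 had the same sign, 262 of them positive.

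Female and male fetuses of both diets were also compared, and no miRNA passed. limma made 0 calls (smallest adjusted p = 0.443), with 17 miRNAs at an unadjusted p under 0.05, and edgeR, DESeq2 and voom made 0. miR-1277-3p came closest (log2 difference 1.34), at 2.30 ± 0.934 RPM in control and 1.52 ± 0.825 RPM in MNR females, against 0 and 0.270 ± 0.468 RPM in males (SD, n = 3). Next were miR-135a-3p (-1.04), at 5.20 ± 2.21 and 7.67 ± 4.50 RPM in females and 18.6 ± 8.11 and 10.2 ± 2.84 RPM in males, and miR-744-3p (-0.77).

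The authors' deposited table gave unadjusted p-values for 3 diet comparisons. In the authors' deposited table the smallest over all fetuses were those of let-7g-5p (0.000183), miR-451a (0.000333), miR-1307-5p (0.000559), miR-129-5p (0.000573) and miR-99b-3p (0.000706). For females the authors' deposited table put miR-106b-3p first (2.43e-05), then miR-18a-5p (0.000475), miR-3064-5p (0.000689), miR-24-1-5p (0.00141) and miR-4484 (0.0022). For males the authors' deposited table put miR-509-3p and miR-548am-3p first (both 1.83e-05), then miR-548h-5p (2.75e-05), miR-22-5p (0.000699) and miR-15b-5p (0.000998). Behind these p-values of the authors' deposited table, miR-509-3p and miR-548am-3p each had 0 reads in control males and 3 in MNR males, at most 1 per fetus, and in females miR-3064-5p had 3 and 0 reads, miR-24-1-5p 4 and 14, and miR-4484 1 and 6. Of the 2234 entries in the authors' deposited table, 139 had a p under 0.05 over all fetuses (117 higher and 22 lower in MNR), 55 in females and 95 in males. After Benjamini-Hochberg adjustment over entries with reads, 0, 1 and 9 entries of the authors' deposited table stayed under 0.05. The 1 female entry was miR-106b-3p. The 9 male entries were not 9 miRNAs but precursor entries of miR-509-3p, miR-548am-3p and miR-548h-5p only. Of these names, miR-509-3p and miR-548am-3p rested on the 3 single reads given above.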

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

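The tests of the scalings on the called miRNAs, of carry-over on scarce miRNAs, of miR-451a against the other erythroid miRNAs and miR-144, and the splits of the fetuses were chosen only after results were seen; the tests of repeat counting, of carry-over on abundant miRNAs and of vessel miRNAs were written down before.

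In RPM, 12 of 13 called miRNAs were higher in MNR and the median log2 difference of all 481 was 0.231. Repeat counting of miRNAs with several precursors is argued against as the cause: with each counted once the median was 0.238, with 17 calls, 13 of them shared. A smaller share of other abundant miRNAs in MNR could lift the rest: of the 11 calls other than miR-451a and miR-122-5p, 0 stayed past the threshold under median-ratio scaling, 0 under TMM scaling and 0 with edgeR, against 4 with DESeq2 and 3 with voom (miR-134 at 0.77, miR-185-5p at 0.73, miR-877-5p at 0.91), and leaving the 5 most abundant out of the scaling moved the shift by 0.12, against 0.22 for median-ratio scaling. The 11 differences shrank but stayed above 0 under median-ratio scaling. They ran from 0.31 ± 0.12 (SE) for miR-129-5p (0.53 ± 0.12 in RPM) to 1.73 ± 0.46 for miR-5585-3p (1.87 ± 0.48 in RPM). The surplus of higher calls and part of each difference thus went with the common shift, and the rest of the difference stays open. Median-ratio and TMM scaling set the typical difference near 0 whatever its cause. They therefore cannot tell a smaller share of abundant miRNAs from a broad rise of the others. miR-451a kept a log2 difference of 0.98 ± 0.20 under median-ratio scaling and was called in 6 of 6 other scalings and fits (median-ratio, TMM, edgeR, edgeR with upper quartile, DESeq2 and voom), which argues against the shift as its whole cause, and diet stays open as an untested biological explanation.

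miR-10a-5p, miR-10b-5p and miR-122-5p were lower in MNR males, and control replicate 6 had the highest level of each; the miRNAs seen in the reads outside these 12 libraries include the same names. Carry-over of the mix of those other reads into control replicate 6 is argued against as the source of its miR-10b-5p excess. Over 15 scarce miRNAs the median of the excess seen over that predicted from miR-10b-5p was 0 (quartiles -0.0034 to 0.0317). miR-122-5p had 7.45 RPM of excess where 414 were predicted, though miR-10a-5p had 735 where 1324 were. The same test on 11 abundant miRNAs (0.0349, quartiles -6.28 to 1.12) did not meet the bound set for it and decided nothing. Because the prediction is scaled to miR-10b-5p, it cannot decide whether the few miR-122-5p reads were carried over at a lower rate. These were 22 reads in the 12 libraries, against 1991754 outside. More vessel or mesenchyme in that piece is argued against as well, since the other 12 vessel miRNAs had a median log2 ratio of -0.508 to the other controls (quartiles -0.946 to 0.0421), against 1.91 for miR-10b-5p. Carry-over from a single other library of different make-up, another position of the cortex piece, and diet could each still be the cause and were not tested. Without control replicate 6 there were 0 male calls. The log2 differences were then -3.13, -1.90 and -2.06 against -4.13, -2.40 and -2.51 for miR-10a-5p, miR-10b-5p and miR-122-5p. That fetus thus does not carry the pattern alone. Control replicate 4, the second-shallowest library (840528 reads), was next highest in each (285.5, 2991 and 4.76 RPM). Control replicate 5, the remaining male control, held 36.1, 2006 and 2.01 RPM. Each control library held 2 to 5 reads of miR-122-5p whatever its depth, so its RPM was highest in the shallow control replicates 4 and 6.

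miR-451a was higher in MNR in 6 of 6 fetuses, and blood left in the tissue could bring it. Against more blood as the whole cause, its log2 ratio to the mean of the 4 other erythroid miRNAs was 2.39 ± 0.419 in controls and 3.05 ± 0.267 in MNR (SD, n = 6; exact permutation p = 0.013). Its ratio to the arms of miR-144, which comes from the same primary transcript, was 3.37 ± 0.325 and 4.08 ± 0.193 (exact permutation p = 0.00216, the smallest these fetuses allow). miR-451a was singled out for the smallest p of the 481 in these same fetuses. That choice favours a higher ratio in MNR, so both p-values overstate the evidence. Among the 4, miR-486-3p was low (0 to 3.9 RPM in controls), where log2(RPM + 1) understates its change. A part of the rise from blood, red cells of another maturity, and an effect of diet on how miR-451a is matured stay open. All 5 erythroid miRNAs had a log2 difference above 0 in RPM, and 4 of them were not called.

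The count of 13 calls over all fetuses was reached by 1 of 100 splits of the 12 fetuses, the real one, and the highest other had 1. A chance split is thus unlikely to give that count. The same holds for the 3 calls under median-ratio scaling (1 of 100, highest other 1). The splits do not bear on any single call, nor on a batch that follows diet, since the labels name no batch. The 2 non-canonical calls (1 of 100, highest other 0) are among the 13, and since few other splits called any miRNA, this count adds nothing on that class. Within a sex the splits are too few for a share under 0.05: in males the real split gave 8 calls (1 of 10 splits, highest other 0), and in females it gave 0 (10 of 10, highest other 0). For the 1 list (70 of 100, highest other 7) chance cannot be excluded. The difference between sexes and sex itself gave 0 calls, which every split reaches (100 of 100 in each, highest other 4 and 1), so the splits test nothing there. Other splits with 4 calls or 7 lists could come from chance or from a structure of the samples. For the lists they could also come from members correlated beyond the preset 0.01 (estimated at 0.429 in the vessel and mesenchyme list). These were not told apart.

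In 24 of 164 group and measure pairs the highest or lowest fetus stood apart from the other 5 by more than a small-sample limit that chance passes in about 1 of 20 (8.2 expected); 15 were in controls and 9 in MNR, with 7 in control replicate 6 and 4 in MNR replicate 4. In control replicate 6 these were miR-10a-5p (820.6 RPM, next 285.5), miR-10b-5p (6908, next 2991), miR-138-5p (1524, next 1080), miR-342-3p (1823, next 1230), miR-18a-5p (74.07, next 21.59), the share of fragments of other RNAs (0.08341%, next 0.05849) and, as the lowest, miR-450a-5p (0, next 2.11). In MNR replicate 4 they were miR-1307-5p (589.6, next 507.1), miR-212-3p (227.1, next 137.3), miR-26b-5p (2394, next 1597) and miR-126-5p (10400, next 6119). Control replicate 3 held 148100 RPM of miR-26a-5p (next 77610), control replicate 4 13.09 RPM of miR-183-5p (next 5.87), and control replicate 2 0.55 RPM of miR-548am-3p (others 0). Control replicate 1 stood apart in miR-200b-3p (7.33, next 1.95) and miR-509-3p (1.47, others 0). Control replicate 5 did in miR-744-3p (14.72, next 7.8), miR-3064-5p (2.01, next 0.73) and miR-24-1-5p (4.68, next 1.95). MNR replicate 2 stood apart in let-7i-5p (11960, next 7645) and miR-708-5p (489.3, next 299.1), MNR replicate 3 in miR-122-5p (1.37, others 0) and as the lowest in miR-548am-3p (0, next 0.78), and MNR replicate 6 in miR-3064-5p (0.81, others 0). The rate of about 1 in 20 holds for normally distributed values. Several flags were a few reads against 0 in the other fetuses, so chance alone can give more than 8.2.

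The pooled read count of the table exceeded the reads of the 12 libraries by 75696036, so it covers libraries not given as columns. Of the outside reads counted once per miRNA, miR-10b-5p held 37.6% (24389546), miR-10a-5p 9.8%, miR-143-3p 6.67%, miR-26a-5p 5.83%, miR-192-5p 5.13% and miR-122-5p 3.07% (1991754, against 22 in the 12 libraries). The placental C19MC names held 1107973 reads outside (1.71%) and 7 reads in the 12 libraries.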

How the results depend on the processing

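Alternatives named without remark were planned; edgeR, DESeq2, voom, TMM, every deposited entry, equal profiles counted as 1, control replicates 3 and 6 left out together, each fetus left out of the depth and composition tests, and the non-canonical calls under alternatives other than no filter were chosen only after results were seen. No paired analysis was possible because replicate numbers follow the order of the records and pair no fetuses. Levels are RPM of counted reads from 1 region at 1 age, so a change in total miRNA per cell would not be seen, and recovery with 3 fetuses per sex and diet was not simulated. Reads are not independent molecules, and near-identical miRNAs could share reads.

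Over all fetuses limma in RPM made 13 calls (12 higher, 1 lower in MNR). The count was 3 under median-ratio scaling, TMM scaling, scaling without the 5 most abundant, edgeR and edgeR with upper quartile (1 higher and 2 lower in each), 7 with voom (5 and 2), 10 with DESeq2 (5 and 5), 7 with sex as a covariate (6 and 1) and 6 with a pseudocount of 0.1. It was 1 (miR-451a) with no filter or a pseudocount of 5, 44 at an adjusted p under 0.1 (36 and 8) and 21 without control replicates 3 and 6 (20 and 1). It was 16 with a mean of at least 10, 15 with equal profiles counted as 1 and 10 with every deposited entry. Leaving out each fetus gave 1 to 26 calls: 26 without control replicate 1, 19 without MNR replicate 2, 18 without control replicate 6, 2 without control replicate 4 or MNR replicate 3, and 1 (miR-451a) without any other. In females the 0 calls became 1 at an adjusted p under 0.1, and 0 to 2 with each fetus left out (2 without MNR replicate 1). In males the 8 calls became 9 under median-ratio scaling (all lower), 8 under TMM scaling, 9 with a pseudocount of 5 (1 higher), 12 at an adjusted p under 0.1 (4 higher), 2 with no filter or DESeq2, 1 with voom or edgeR with upper quartile, 4 with equal profiles counted as 1, 22 with every deposited entry (2 higher, 20 lower), and 0 with a mean of at least 10, a pseudocount of 0.1, males alone, edgeR, or without control replicates 3 and 6. Leaving out each fetus gave 0 to 10 male calls: 10 without control replicate 3, 9 without MNR replicate 2, 7 without control replicate 5, 4 without MNR replicate 6, 1 without MNR replicate 4 and 0 without any other. The 2 non-canonical calls became 1 (miR-451a) under median-ratio scaling, TMM scaling, scaling without the 5 most abundant, no filter, either pseudocount, edgeR, edgeR with upper quartile and every deposited entry, and 1 to 3 with each fetus left out (1 without control replicate 2, 3, 4 or 5 or MNR replicate 1, 3, 4, 5 or 6). The 1 list past the threshold became 0 with an estimated correlation and 3 without control replicates 3 and 6, and 0 to 3 with each fetus left out: 0 without control replicate 6 or MNR replicate 2, 2 without control replicate 5 or MNR replicate 6, and 3 without MNR replicate 4. Of 7 depth and composition measures 4 passed, and 1 to 4 did with each fetus left out: 1 without control replicate 2, 4 or 5 or MNR replicate 3 or 5, and 2 without MNR replicate 4. The interaction and sex tests stayed at 0 throughout.

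For the named miRNAs 1546 of 2009 alternative values stayed the same, 332 were weaker, 29 stronger and 102 turned sign, the last in 18 of 78 results. For the lists 285 of 306 stayed the same and 12 turned direction. The miRNAs that turned had log2 differences near 0 over all fetuses and were never called. The other scalings lower the MNR libraries on average relative to controls (all but MNR replicate 2, whose factor was below 1), which takes mean differences just above 0 below it; the cause of the other turns was not tested. Median-ratio scaling gave -0.14 for miR-9-5p, -0.14 for miR-181a-5p, -0.12 for let-7f-5p, -0.052 for miR-127-3p, -0.0020 for miR-138-5p, -0.075 for miR-342-3p, -0.086 for miR-146a-5p, -0.049 for miR-204-5p, -0.18 for miR-183-5p, -0.14 for miR-93-5p, -0.055 for miR-103a-3p, -0.21 for miR-181c-5p, -0.044 for miR-664-3p. TMM scaling gave -0.12 for miR-9-5p, -0.12 for miR-181a-5p, -0.10 for let-7f-5p, -0.036 for miR-127-3p, -0.059 for miR-342-3p, -0.070 for miR-146a-5p, -0.032 for miR-204-5p, -0.17 for miR-183-5p, -0.13 for miR-93-5p, -0.039 for miR-103a-3p, -0.19 for miR-181c-5p, -0.027 for miR-664-3p. edgeR gave -0.11 for miR-9-5p, -0.13 for miR-181a-5p, -0.12 for let-7f-5p, -0.055 for miR-127-3p, -0.011 for miR-138-5p, -0.10 for miR-342-3p, -0.035 for miR-146a-5p, -0.090 for miR-204-5p, -0.16 for miR-93-5p, -0.048 for miR-103a-3p, -0.20 for miR-181c-5p, -0.12 for miR-664-3p. DESeq2 gave -0.12 for miR-9-5p, -0.13 for miR-181a-5p, -0.13 for let-7f-5p, -0.060 for miR-127-3p, -0.013 for miR-138-5p, -0.11 for miR-342-3p, -0.041 for miR-146a-5p, -0.097 for miR-204-5p, -0.0061 for miR-183-5p, -0.17 for miR-93-5p, -0.055 for miR-103a-3p, -0.21 for miR-181c-5p, -0.13 for miR-664-3p. edgeR with upper quartile gave -0.020 for miR-9-5p, -0.030 for miR-181a-5p, -0.014 for let-7f-5p, -0.066 for miR-93-5p, -0.11 for miR-181c-5p, -0.018 for miR-664-3p. voom gave -0.17 for miR-9-5p, -0.22 for miR-181a-5p, -0.089 for let-7f-5p, -0.029 for miR-127-3p, -0.21 for miR-93-5p, -0.053 for miR-103a-3p, -0.31 for miR-181c-5p. Scaling without the 5 most abundant gave -0.039 for miR-9-5p, -0.036 for miR-181a-5p, -0.017 for let-7f-5p, -0.098 for miR-183-5p, -0.044 for miR-93-5p, -0.11 for miR-181c-5p. A pseudocount of 0.1 gave -0.017 for miR-183-5p. Leaving out control replicates 3 and 6 gave -0.097 for miR-181a-5p, 0.13 for miR-212-3p, -0.040 for miR-183-5p, -0.14 for miR-93-5p, -0.17 for miR-181c-5p. Adjusted p of lists that turned direction was 0.90 for neuron-enriched miRNAs under upper quartile scaling and 0.60 for the miR-17-92 family without control replicates 3 and 6. With each fetus left out the log2 difference ran as follows: miR-181a-5p -0.027 to 0.13, miR-191-5p -0.16 to 0.030, miR-212-3p -0.21 to 0.078, miR-146a-5p -0.0061 to 0.32, miR-126-5p -0.17 to 0.12, miR-182-5p -0.31 to 0.056, miR-183-5p -0.26 to 0.21, miR-93-5p -0.021 to 0.13, miR-410 -0.19 to 0.011, miR-181c-5p -0.060 to 0.078. The adjusted p of lists that turned ran from neuron-enriched 0.37 to 0.99, muscle 0.61 to 0.95, miR-17-92 family 0.67 to 0.98, insulin and lipid 0.46 to 0.96. The difference in total reads (MNR minus control) ran from -233400 to 43750, above 0 without control replicate 2 or 3.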

Other observations

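The test of the non-canonical share without miR-451a and the miRNAs named in this part were chosen only after results were seen.

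Just outside the threshold over all fetuses, the brain-enriched miR-383 was at 174 ± 94.5 RPM in controls and 336 ± 69.9 RPM in MNR (SD, n = 6; log2 difference 1.12, limma adjusted p = 0.0528). In the let-7 family the 5 members past the threshold adjusted over the list alone were all -5p arms (let-7i-5p, let-7d-5p, let-7b-5p, let-7g-5p and let-7a-5p). In RPM 14 of 17 members had a log2 difference above 0. Among the others, none past the threshold, let-7c was at 6830 ± 4146 RPM in controls, with control replicate 6 at 15015 RPM, and 6066 ± 857 RPM in MNR, and its log2 difference was -0.02 in RPM and -0.24 under median-ratio scaling. let-7b-5p was at 3206 ± 885 and 4608 ± 689 RPM (0.55, adjusted p = 0.0667), and the opposite arm let-7b-3p at 94.7 ± 13.6 and 80.3 ± 6.35 RPM (-0.23, adjusted p = 0.374). The miR-212 and miR-132 pair, cut from 1 transcript, had log2 differences of -0.04 and 0.48, neither past the threshold.

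In RPM, no MNR fetus overlapped any control in 16 of 481 miRNAs, 15 above and 1 below, where chance gives 0.216%, or 1.04. That chance value takes no account of the common upward shift in RPM, so the excess over it cannot be read for single miRNAs. Among the called miRNAs, those without overlap were miR-451a, let-7i-5p, miR-134, miR-377-5p, miR-154-5p, miR-1307-5p and miR-125a-5p above and miR-122-5p below.

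A hypothesis is that restriction of the mother may raise the share of miRNAs that bypass Drosha or Dicer as a class and not through miR-451a alone. Without miR-451a the share was 0.224 ± 0.0223% in MNR and 0.162 ± 0.0310% in controls (SD, n = 6; exact permutation p = 0.00216, the smallest these fetuses allow). The remaining miRNAs were miR-320a, with a log2 difference of 0.39 ± 0.15 (SE) under median-ratio scaling, miR-320c (0.49), miR-320b (0.28) and miR-484 (0.10), none past the threshold there. The share without miR-451a thus came from the near-identical miR-320 names, led by miR-320a (mean 668 RPM over all fetuses), and from miR-484 (415 RPM). This share takes in the common upward shift in RPM (median log2 difference of all tested miRNAs 0.23). Its permutation p therefore cannot tell a rise of this class from that shift, and whether it stands for a class was not tested. Fragments of other RNAs rose in share as well (exact permutation p = 0.00866), so a difference in RNA quality between diets stays open for this class. A spike-in or RNA integrity values for each fetus would tell a shift of all miRNAs from a shift of this class.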
